A study of Mus musculus with 11 samples.

How the data were processed

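The 11 libraries came from isolated mouse glomeruli, whose RNA was treated with DNase and sequenced if its integrity value was above 7.5, per the labels. The labels describe male db/db mice on the BKS background and db/m littermates of the same sex and age, while the strain field names C57BL/6J, and they name 2 sequencing sites without assigning libraries to them. Reads were processed with BWA and limma against the mouse build mm10, per the submitters' processing notes, with no versions. How reads were assigned to transcripts, and whether strand was used, is not given in the sources used here.

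The deposited counts were whole numbers of reads for each of 22320 RefSeq transcripts, in a table of 15 count columns, of which 4 matched no sample and were not used. The authors' deposited log2 values were the log2 of the same counts plus a constant per library, which scaled each library to the largest total. Each transcript reached a count of at least 100 in some column of the deposited table (at least 69 over the 11 libraries), no cell was 0, and 13 blank cells were treated as 0. No transcript of the mitochondrial chromosome was listed. Gene symbols that a spreadsheet had turned into dates (50 transcripts) were restored by transcript identifier.

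Counts were summed to 13734 genes. Of these, 4562 had more than 1 transcript (up to 25), and in 75.1% of them the highest pair of transcripts had totals within 10% of each other, so a sum counts shared reads more than once. The precision of a sum is therefore lower than its count implies. Total counts over transcripts ran from 35369703 to 44244460 per library. Counting only the highest transcript of each gene, the 10 most abundant genes took 4.31% to 5.29% of the counts. Genes that share reads with near-identical copies (class I histocompatibility genes, globins, Cyp4a genes, D17H6S56E-5) are uncertain.

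Libraries were grouped by their labels into db/db puerarin (n = 3), db/db vehicle (n = 4) and db/m vehicle (n = 4), and named by the number in their titles. The labels do not say whether each library came from 1 animal or from a pool. P-values therefore cover the spread between these samples, which may be technical in part. No pair of libraries in a group agreed within sampling noise. Samples, tests, gene lists and further settings were fixed before the data were examined. The design assumed limma unless the files held counts. They did, so edgeR was used, as the design provided.

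The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM factors) in R 4.3.3, fitted to the counts of all 11 libraries with group and name form as terms. A gene needed a count of at least 1 in 3 libraries, which removed none. The fit had 7 residual degrees of freedom and a prior of 3.14. Two-sided p-values were adjusted by Benjamini-Hochberg, and a gene passed under an adjusted p of 0.05. CPM values are means ± SD over the libraries of a group. Single values for Gnai1 and Lepr were also tested by exact two-sided permutation of log2 CPM.

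Simulated data were made from the real means, dispersions and library sizes, with 200 of 13734 genes changed. The podocyte list genes outside these 200 were lowered 1.5-fold as well. They enter the totals of calls below, but not the shares found. For db/db against db/m on vehicle, 20% of genes changed 1.5-fold, 78% changed 2-fold and 94% changed 3-fold were found, with 5 false calls among 163. For puerarin against vehicle, the shares were 14%, 70% and 88%, with 5 false calls among 146. For puerarin-treated db/db against db/m, they were 32%, 60% and 94%, with 8 false calls among 159. In each simulation the changed podocyte list was called and 0 other lists were. That call does not show whether a smaller change of a list would be found. Genes were simulated independently, whereas in the real data the estimated correlation within a list reached 0.92 (oxidative phosphorylation). The simulations therefore do not show how often list calls are false in these data.

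There were 29 gene lists. The cell and tissue lists were podocyte, glomerular endothelial, mesangial, proximal tubule, loop and distal tubule, collecting duct, myeloid, lymphocyte and erythroid. The pathway lists were inhibitory G-protein and cAMP, CREB targets, extracellular matrix, inflammation, interferon, complement, angiogenic, actin and adhesion, antioxidant, NADPH oxidase, oxidative phosphorylation, fatty acid oxidation, lipid synthesis and uptake, glycolysis, autophagy, endoplasmic reticulum stress, apoptosis and p53, cell cycle, immediate early and stress, and ribosomal protein. Each was tested with camera of limma 3.58.1 (preset correlation 0.01, two-sided, Benjamini-Hochberg over the 29 lists of a comparison), with an estimated correlation and with fry. A list level is the mean over members of log2 CPM minus its mean over the 11 libraries, and the tubule level is the mean of the 3 tubule lists.

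The genes named in the text came from a fixed rule. For each comparison it took up to 12 genes per direction with the largest fold change past the test and the same sign within both name forms, leaving out predicted models, pseudogenes and the lowest 25% of genes by expression. Where fewer than 5 passed in a direction, those with the smallest p filled the number to 5. It added up to 4 members of each list with the smallest p, a fixed set of genes (Gnai1, Gnai2, Gnai3, Lepr, Nphs1, Wt1, Synpo, Nox4, Sirt1, Prkaca and Prkacb), and any gene past both tests of the reversal. Some genes that the rule took are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

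The settings also run, as chosen in advance, were other filters, scalings and pseudocounts (0.25, 1 and 4 for limma), DESeq2 1.42.0, limma with quantile normalization, library weights or no trend, no name form term, a replicate block, each name form alone, only the groups compared, the highest transcript per gene, and leaving out each library in turn. Chosen after seeing the data were relative log expression factors, robust edgeR, limma on the authors' log2 values, the tubule level as a covariate, list tests in the group-tag libraries alone, and fits without db/db puerarin 2 and 3 or without db/m vehicle S184 and S185.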

Results

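RNA from isolated mouse glomeruli was sequenced as 11 libraries in 3 groups. Mice homozygous for the db allele of the leptin receptor (db/db), a model of type 2 diabetes with kidney disease, received vehicle (5% DMSO, n = 4) or puerarin, an isoflavone glycoside from kudzu root (20 mg per kg body weight per day by gavage, n = 3). Heterozygous db/m littermates on vehicle were the non-diabetic controls (n = 4). Treatment started at 10 weeks of age and lasted 6 weeks, per the labels. The deposited table gave reads per RefSeq transcript, and the 11 libraries had total counts of 35369703 to 44244460. These were summed to 13734 genes and are given as counts scaled to library size with TMM factors (CPM). Library titles came in 2 forms, an S number (5 libraries) or a group tag with a number (6 libraries), and both occurred in every group. The name form was a covariate, and differences within each form are given for the main genes. The labels call the mice male, but db/db puerarin 2 and 3 had 528.5 and 819 CPM of Xist, the RNA of the inactive X chromosome, against 0.5 to 6.5 CPM in the other 9 libraries. Their Y-linked Ddx3y was at 3.1 and 0.9 CPM, against 50.3 to 85.2 CPM. Xist and Ddx3y were chosen after their values were seen.

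**Figure D1:**
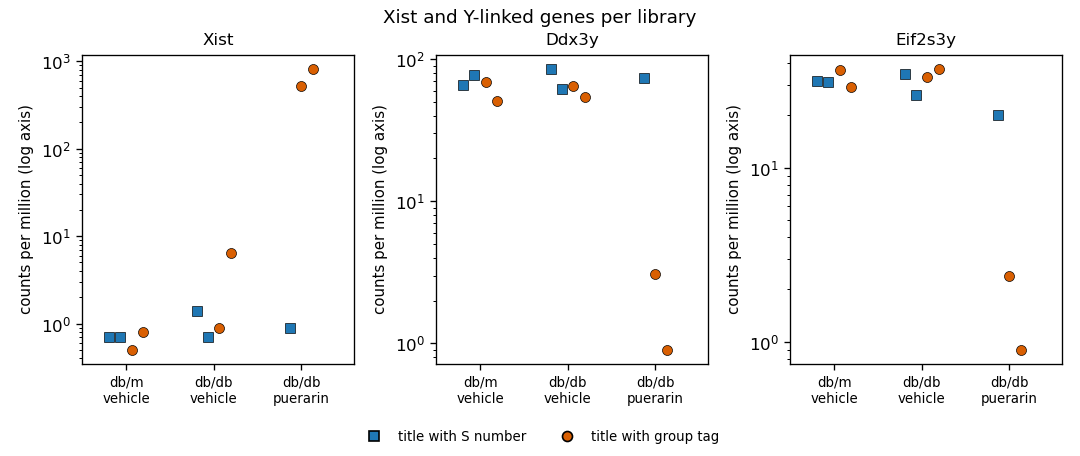
Xist, Ddx3y and Eif2s3y in each of the 11 libraries, in CPM on a log axis, by group, with squares for S-number titles and circles for group-tag titles. The puerarin libraries 2 and 3 had Xist at 528.5 and 819 CPM and Eif2s3y at 2.4 and 0.9 CPM.

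The comparison of db/db with db/m mice on vehicle addressed what the diabetic genotype changed in glomeruli. Expression of 6 genes fell in db/db glomeruli and none rose past the test. Foxc2, a forkhead transcription factor of podocyte development, was at 97.6 ± 9.76 CPM in db/db (SD, n = 4) and 160 ± 25.4 CPM in db/m (SD, n = 4). Aebp1, which encodes a collagen-binding matrix protein, was at 363 ± 26.5 against 582 ± 61.6 CPM. Kcnj12, an inward-rectifier potassium channel, was at 33.7 ± 3.78 against 58.2 ± 2.99 CPM. Dkk3, a secreted member of the Dickkopf family of Wnt modulators, was at 5.27 ± 0.619 against 12.8 ± 0.922 CPM. The noncoding RNA gene C130021I20Rik and the organic anion transporter gene Slc22a7 were also lower, the latter at 0.844 ± 0.181 against 4.94 ± 2 CPM.

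In edgeR's quasi-likelihood test, Foxc2 fell by 0.70 on the log2 scale (SE 0.08, Benjamini-Hochberg adjusted p = 0.0398). Its difference was -0.79 within the S-number libraries and -0.61 within the group-tag libraries. Kcnj12 had a log2 fold change of -0.79 (SE 0.1, edgeR adjusted p = 0.0398), with -0.71 and -0.87 within the 2 name forms. Aebp1 had a log2 fold change of -0.68 (SE 0.09, edgeR adjusted p = 0.0493), with -0.83 and -0.53. Dkk3 had -1.28 (SE 0.13, edgeR adjusted p = 0.0232), C130021I20Rik -0.85 (SE 0.11, edgeR adjusted p = 0.0398) and Slc22a7 -2.53 (SE 0.34, edgeR adjusted p = 0.0493). Over 33 other settings Slc22a7 ranged from -2.9 to -0.85 and kept its call in 15. All 4 db/db vehicle libraries lay below all 4 db/m libraries for each of the 6 genes. Dkk3, C130021I20Rik and Slc22a7 fell outside the rule for named genes and were chosen after their values were seen. Foxc2 lies on chromosome 8 (121116170 to 121118894, plus strand, mm10) and Aebp1 on chromosome 11 (5861865 to 5872248, plus strand). Kcnj12 lies on chromosome 11 (61022563 to 61073267, plus strand), Dkk3 on chromosome 7 (112116018 to 112159057, minus strand) and Slc22a7 on chromosome 17 (46432184 to 46438477, minus strand). C130021I20Rik lies on chromosome 2 (33641192 to 33645663, plus strand), beside the minus-strand gene Lmx1b (33564535 to 33640511), whose log2 fold change was -0.57 (edgeR adjusted p = 0.155).

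**Figure D2:**
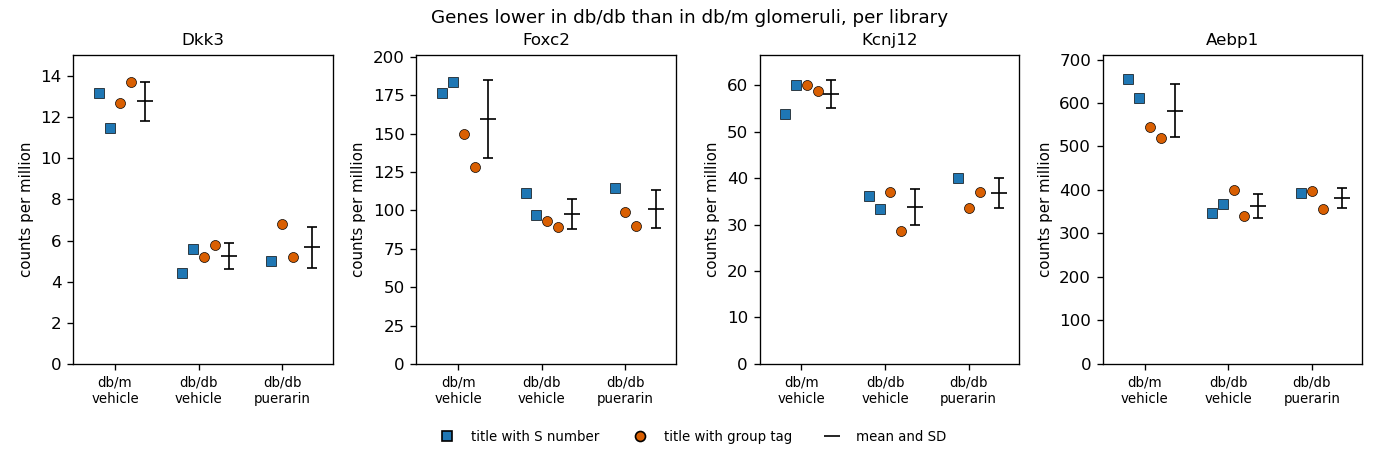
CPM of Dkk3, Foxc2, Kcnj12 and Aebp1 in each library of the 3 groups, with group means and SD; squares mark S-number titles and circles group-tag titles. The db/db vehicle means were 5.27, 97.6, 33.7 and 363 CPM, against 12.8, 160, 58.2 and 582 CPM in db/m.

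Of the genes that did not pass, the smallest p-values among higher values belonged to Lgals1 (galectin-1, log2 fold change 1.09), Plxnc1 (a semaphorin receptor, 0.79), Man2a1 (a Golgi mannosidase, 0.73) and Flnc (filamin C, 0.59), each with an edgeR adjusted p of 0.0647. D17H6S56E-5 was at 1.37 (edgeR adjusted p = 0.0651) and is uncertain, because it shares reads with near-identical copies. Acpp, an acid phosphatase gene, was at -0.66 (edgeR adjusted p = 0.051). H2-Q5, at -0.64 (edgeR adjusted p = 0.0647), belongs to a class I family with near-identical members and is uncertain as well.

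Podocyte genes fell as a list (median log2 fold change -0.17, camera adjusted p = 4.3e-07 with a preset correlation of 0.01). With an estimated correlation the adjusted p of the podocyte list was 0.659. Podocyte levels of single libraries overlapped, at -0.34 to 0.06 in db/db and -0.06 to 0.24 in db/m. The lowest was in db/db vehicle 3, the library with the highest tubule level (1.02). Of 34 measured podocyte genes, 28 had a lower mean in db/db, 1 passed the test over all genes (Foxc2), and 8 passed when adjusted over the list alone, all lower. The transcription factor gene Lmx1b had a log2 fold change of -0.57 (edgeR adjusted p = 0.155), and Wt1 and Synpo, which encodes the actin-binding protein synaptopodin, had -0.37 and -0.33 (edgeR adjusted p = 0.303 and 0.261). The slit diaphragm gene Nphs1 was at -0.03 (edgeR adjusted p = 0.944). The podocyte call held in camera without each of the 11 libraries in turn. The glomerular endothelial (camera adjusted p = 0.797) and mesangial lists (camera adjusted p = 0.319) were not called. Gpihbp1, an endothelial carrier of lipoprotein lipase, was at 0.90 (edgeR adjusted p = 0.129), and Ednrb, the endothelin B receptor, at 1.02 (edgeR adjusted p = 0.0918).

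Myeloid genes rose as a list in db/db (median log2 fold change 1.14, camera adjusted p = 3.72e-10; adjusted p = 0.659 with an estimated correlation). All 25 measured members had a higher mean, none passed over all genes and 3 passed when adjusted over the list alone. The complement component genes C1qa, C1qb and C1qc, made by macrophages, had log2 fold changes of 3.43, 3.96 and 3.57 (edgeR adjusted p = 0.215, 0.205 and 0.199). The myeloid level was highest in db/db vehicle 1, at 2.26 on the log2 scale against the mean of the 11 libraries, followed by db/db vehicle 3 at 0.6. The group-tag libraries of db/m were at -1.11 and -0.71. Within the S-number libraries there was no rise, with -0.13 and -0.19 in db/db and -0.18 and -0.15 in db/m. C1qa was at 93.3 CPM in db/db vehicle 1, 22.7 in db/db vehicle 3 and 1 to 12.4 in the other 9 libraries. Without db/db vehicle 1 the myeloid median was 0.54, with 23 of 25 members positive (camera adjusted p = 0.000741). Cell cycle genes also rose as a list (median 0.35, 20 of 22 members higher, camera adjusted p = 3.28e-07; adjusted p = 0.659 with an estimated correlation), with 7 members past the test when adjusted over the list alone. Cdk1 was at 2.61 ± 1.34 against 0.716 ± 0.32 CPM (log2 fold change 1.87, edgeR adjusted p = 0.182). Mki67, the proliferation marker, was at 1.27 (edgeR adjusted p = 0.214).

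Genes of fatty acid oxidation rose as a list (median 0.24, 31 of 32 members higher, camera adjusted p = 1.12e-05; adjusted p = 0.659 with an estimated correlation). Its member Cyp4a14, a fatty acid hydroxylase that shares reads with close paralogs and is uncertain, was at 2.75 (edgeR adjusted p = 0.138). Antioxidant genes rose as a list (median 0.24, 26 of 29 higher, camera adjusted p = 8.92e-05; adjusted p = 0.659 with an estimated correlation), and the metallothionein Mt2 was at 1.03 (edgeR adjusted p = 0.135). Collecting duct genes were higher (median 0.48, camera adjusted p = 0.00266; adjusted p = 0.659 with an estimated correlation). These 3 calls and those for myeloid and cell cycle genes held without each of the 11 libraries. Loop and distal tubule genes were higher as well (median 0.42, camera adjusted p = 0.00205; adjusted p = 0.724 with an estimated correlation), but not without db/m vehicle S185 (camera adjusted p = 0.0934) or with the tubule level as a covariate (0.267), a setting chosen after seeing the data. The mean level of the 3 tubule lists, against the mean of all libraries, was 1.02 in db/db vehicle 3 and -0.89 in db/m vehicle S185, and -0.17 to 0.35 in the other 6 libraries of this comparison. Proximal tubule genes were not called (camera adjusted p = 0.904), but were called lower without db/db vehicle 3 (0.000151) and with the tubule covariate (9.79e-05). The covariate is the mean of the 3 tubule lists, so with it their effects must nearly cancel. Values of these lists with the covariate therefore decide nothing.

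The other calls of this comparison were each lost without at least 1 library, and none held with an estimated correlation. Oxidative phosphorylation was higher (median 0.17, camera adjusted p = 0.000911; adjusted p = 0.873 with an estimated correlation), with a camera adjusted p of 0.129 without db/db vehicle S153, 0.456 without db/m vehicle S185 and 0.106 without db/db vehicle 3. With the tubule level as a covariate it was 0.722 and turned downward, and the glycolysis (camera adjusted p = 0.103), interferon (0.267), lymphocyte (0.106) and ribosomal protein calls (0.361) were lost. Glycolysis was higher (median 0.19, camera adjusted p = 0.00849; adjusted p = 0.659 with an estimated correlation), with 0.0816 without db/m vehicle S185 and 0.095 without db/m vehicle 2. Inflammation was higher (median 0.16, camera adjusted p = 0.0228; adjusted p = 0.659 with an estimated correlation), with 0.109 without db/m vehicle S184, 0.677 without db/db vehicle 1 and 0.135 without db/m vehicle 2. Its leading members were the adhesion molecules Sele at 0.97 and Icam1 at 0.52 (edgeR adjusted p = 0.149 and 0.336). Interferon genes were lower (median -0.1, camera adjusted p = 0.022; adjusted p = 0.771 with an estimated correlation), led by Ifi44 at -0.89 (edgeR adjusted p = 0.0647). That call was lost without db/db vehicle S152 (camera adjusted p = 0.173), db/m vehicle S185 (0.0816), db/db vehicle 3 (0.0946) or db/m vehicle 3 (0.114). Ribosomal protein genes were higher by a median of 0.09 (camera adjusted p = 0.0228; adjusted p = 0.873 with an estimated correlation). That call was lost without db/db vehicle S153 (camera adjusted p = 0.726), db/m vehicle S185 (0.0818), db/db vehicle 3 (0.112), db/m vehicle 2 (0.095) or db/m vehicle 3 (0.0567). Lymphocyte genes were lower (6 measured, median -0.44, camera adjusted p = 0.0417; adjusted p = 0.659 with an estimated correlation). That call was lost without db/db vehicle S153 (camera adjusted p = 0.0658), db/m vehicle S184 (0.0653), db/m vehicle S185 (0.157), db/db vehicle 3 (0.125) or db/m vehicle 3 (0.127).

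Lists without a call in this comparison (camera adjusted p) were actin and adhesion (0.598), angiogenic (0.145), apoptosis and p53 (0.133, but a fry adjusted p of 0.0133), autophagy (0.998), complement (0.3), CREB targets (0.364), extracellular matrix (0.319), endoplasmic reticulum stress (0.451), erythroid (0.451), immediate early and stress (0.689), lipid synthesis and uptake (0.319) and NADPH oxidase (0.143). Among matrix genes, 2 were higher and 3 lower when adjusted over the list alone. They were led by Col8a1, a short-chain collagen (log2 fold change 0.96), Col6a1 (-0.76), the protease inhibitor Timp3 (0.50) and the growth factor Tgfb2 (-0.59), with edgeR adjusted p = 0.111, 0.135, 0.138 and 0.168. Lrg1 and Adm, which encode secreted vascular regulators, were at 1.68 and 1.10 (edgeR adjusted p = 0.138 and 0.0963). The sterol regulator Srebf2 was at -0.30 (edgeR adjusted p = 0.182). Nox4, an oxidase of kidney cells, was at 161 ± 86.9 against 107 ± 95.4 CPM (edgeR adjusted p = 0.71), and the deacetylase gene Sirt1 at 0.01 (edgeR adjusted p = 0.982).

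At an unadjusted p under 0.05, edgeR found 1418 genes, 755 higher and 663 lower, and DESeq2 called 290 (150 higher and 140 lower). Groups were fully separated for 681 genes, 4.96% against 2.86% by chance. The count of 6 became 8 without db/db puerarin S144 or puerarin 2 (4 shared with the 6 in each), 1 without db/db vehicle S152 or db/m vehicle 2 (shared), and 82 without db/db vehicle 1 (6 shared). It was 0 in edgeR without db/db vehicle S153, db/m vehicle S184, db/m vehicle S185, db/db vehicle 3, db/db puerarin 3 or db/m vehicle 3. Without db/m vehicle S184 and S185, an alternative chosen after seeing the data, edgeR called 0 genes (1225 at an unadjusted p under 0.05), and without db/db puerarin 2 and 3 it called 2.

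The comparison of puerarin with vehicle in db/db mice addressed what the drug changed. The libraries with high Xist, db/db puerarin 2 and 3, were both in the puerarin group. Sex was not a term of any fit. Only db/db puerarin S144 had low Xist in the puerarin group (0.9 CPM), and 1 library cannot separate sex from the drug. No gene passed the test (smallest edgeR adjusted p = 0.526), and the genes below are given as values. Acta2, which encodes smooth muscle actin, was at 212 ± 117 CPM with puerarin (SD, n = 3) and 106 ± 68.1 CPM with vehicle (SD, n = 4), a log2 fold change of 0.75 (SE 0.11, edgeR adjusted p = 0.526). Its difference was 0.73 within the S-number and 0.77 within the group-tag libraries. The contractile genes Tagln and Tpm2 were at 0.56 and 0.64 and the Tudor domain gene Tdrd5 at 0.62 (edgeR adjusted p = 0.862 for each). Daam2, a formin, was at 0.46, and the genes with the smallest p among lower values were Fam214a (-0.66), Ccdc181 (-0.49), the sugar transporter gene Slc45a4 (-0.34), Mctp1 (-0.53) and Olfm1 (-0.44), all with an edgeR adjusted p of 0.967.

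As lists, 16 of 29 were called, none of them with an estimated correlation, and each was lost without at least 1 library. The mesangial list was called up (camera adjusted p = 0.00417; adjusted p = 0.696 with an estimated correlation), although its median log2 fold change was -0.07. With no name form term that call was lost (camera adjusted p = 0.696). Acta2, Tagln, Myh11 (smooth muscle myosin, 0.58) and Rgs5 (a pericyte regulator of G-protein signalling, 0.47) were the 4 members past the test when adjusted over the list alone. Loop and distal tubule genes fell as a list (median -0.61, 16 of 16 lower, camera adjusted p = 9.74e-07; adjusted p = 0.696 with an estimated correlation), with Umod (uromodulin) at -0.72 and Egf at -0.63 (edgeR adjusted p = 0.967 for both). Collecting duct genes (median -0.4, camera adjusted p = 8.56e-05; adjusted p = 0.696 with an estimated correlation) and proximal tubule genes (median -0.39, 25 of 27 lower, camera adjusted p = 0.00229; adjusted p = 0.75 with an estimated correlation) were lower too. The loop and distal (camera adjusted p = 0.14) and collecting duct calls (0.228) were lost with no name form term. The proximal tubule genes Kap and Slc7a13 were at -2.31 and -1.93 (edgeR adjusted p = 0.967 for both). Neither value was separated from a sex difference between the groups, which was not tested. Glomerular endothelial genes were higher (median 0.14, 22 of 26, camera adjusted p = 0.000327; adjusted p = 0.696 with an estimated correlation) and podocyte genes were higher (median 0.08, 29 of 34, camera adjusted p = 0.000952; adjusted p = 0.73 with an estimated correlation). Synpo was at 0.20 (edgeR adjusted p = 0.967).

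The tubule level was -1.31 in db/db puerarin S144, the lowest of all libraries, and 1.02 in db/db vehicle 3, the highest. Without db/db puerarin S144 the calls of the loop and distal (camera adjusted p = 0.788), collecting duct (0.748), proximal tubule (0.894), endothelial (0.386), podocyte (0.788) and mesangial lists (0.176) were lost, and the collecting duct list turned upward. Without db/db vehicle 3 the calls of the proximal tubule (camera adjusted p = 0.455), endothelial (0.604), podocyte (0.383) and mesangial lists (0.977) were lost, and the proximal tubule list turned upward and the mesangial list downward. With the tubule level as a covariate the calls of the endothelial (camera adjusted p = 0.944), podocyte (0.944) and mesangial lists (0.808) were lost too. The loop and distal (0.154) and collecting duct calls (0.205) were lost with it, and the proximal tubule list turned upward (1e-07). Because the covariate is built from these tubule lists, their own values with it decide nothing. Myeloid genes were lower with puerarin (median -1.17, 25 of 25, camera adjusted p = 5.76e-09; adjusted p = 0.696 with an estimated correlation), and C1qa was at -1.95 (edgeR adjusted p = 0.967). In the S-number libraries the myeloid level was -0.26 with puerarin and -0.13 and -0.19 with vehicle. In the group-tag libraries it was -0.48 and 0.35 with puerarin and 2.26 and 0.6 with vehicle. Without db/db vehicle 1, the library with the highest myeloid level (2.26), the myeloid median was -0.29 and the call was lost (camera adjusted p = 0.248).

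**Figure D3:**
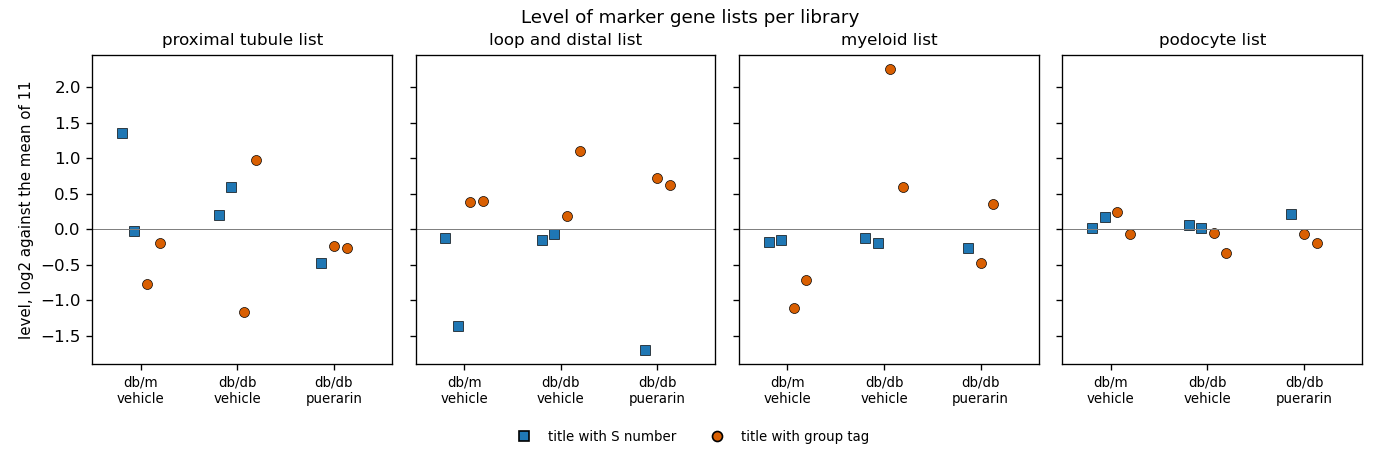
Level of the proximal tubule, loop and distal tubule, myeloid and podocyte lists in each library, as the mean log2 difference from the mean of the 11 libraries, by group; squares mark S-number titles and circles group-tag titles. The loop and distal level was lowest in db/db puerarin S144 (-1.7) and highest in db/db vehicle 3 (1.1), and the myeloid level was highest in db/db vehicle 1 (2.26).

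Metabolic lists were called lower with puerarin in the main fit, but not when the tubule level was a covariate, an alternative chosen after seeing the data. With it, oxidative phosphorylation (camera adjusted p = 1.59e-08), fatty acid oxidation (0.00821) and antioxidant genes (0.0202) were called higher, and glycolysis (0.151) and NADPH oxidase (0.205) were not called. The covariate fit was run with the preset correlation only. For oxidative phosphorylation the correlation estimated in the main fit was 0.92, so these calls do not show a rise with puerarin. In the main fit, glycolysis had a median of -0.24 (camera adjusted p = 0.000109; adjusted p = 0.696 with an estimated correlation), with the hexokinase gene Hk1 at -0.30 (edgeR adjusted p = 0.967), and was lost without db/db puerarin S144 (camera adjusted p = 0.176). Oxidative phosphorylation had a median of -0.14 (camera adjusted p = 0.00152; adjusted p = 0.75 with an estimated correlation). It turned upward without db/db puerarin S144 (camera adjusted p = 0.0362) and was lost without db/db vehicle S153 (0.2) or db/db vehicle 3 (0.465). Fatty acid oxidation had a median of -0.16 (camera adjusted p = 0.0307; adjusted p = 0.75 with an estimated correlation). It turned upward without db/db puerarin S144 (camera adjusted p = 0.748) or db/db vehicle 3 (0.977) and was lost without db/db vehicle S152 (0.0778), db/db vehicle S153 (0.226) or db/db puerarin 3 (0.0793). Antioxidant genes had a median of -0.12 (camera adjusted p = 0.0474; adjusted p = 0.75 with an estimated correlation). That list turned upward without db/db puerarin S144 (camera adjusted p = 0.748) and was lost without db/db vehicle S153 (0.206), db/m vehicle S185 (0.0757), db/db vehicle 3 (0.907), db/db puerarin 3 (0.0824) or db/m vehicle 3 (0.0526). NADPH oxidase genes had a median of -0.29 (camera adjusted p = 0.0316; adjusted p = 0.696 with an estimated correlation) and were lost without db/db puerarin S144 (0.318), db/db vehicle 1 (0.603) or db/db puerarin 2 (0.137).

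Angiogenic genes were higher (median 0.09, camera adjusted p = 0.00678; adjusted p = 0.696 with an estimated correlation), with Adm at 0.75 and endothelin-1 (Edn1) at 0.49 (edgeR adjusted p = 0.967 for both). That call was lost without db/db puerarin S144 (camera adjusted p = 0.0951) or db/db vehicle 3 (0.3), and with the tubule level as a covariate (0.326). Ribosomal protein genes were higher by a median of 0.04 (camera adjusted p = 0.018; adjusted p = 0.75 with an estimated correlation). They were lost without db/db vehicle S152 (camera adjusted p = 0.31) or db/db vehicle 1 (0.616), and turned downward without db/db puerarin 2 (0.5). Erythroid genes, mostly near-identical globin pairs that are uncertain, were lower (median -0.28, camera adjusted p = 0.0302; adjusted p = 0.696 with an estimated correlation). They were lost without db/m vehicle S184 (camera adjusted p = 0.0527), db/db vehicle 1 (0.471), db/db vehicle 3 (0.0752) or db/db puerarin 3 (0.504). CREB targets were called up (median 0.04, camera adjusted p = 0.0474; adjusted p = 0.696 with an estimated correlation), with the cAMP-responsive transcription factor gene Crem at 0.34 and the cAMP phosphodiesterase gene Pde4d at 0.29 (edgeR adjusted p = 0.967 for both). That call was lost without db/db vehicle S153 (camera adjusted p = 0.214), db/m vehicle S184 (0.0708), db/m vehicle S185 (0.0527), db/db vehicle 1 (0.101), db/db vehicle 3 (0.359), db/db puerarin 2 (0.69), db/m vehicle 2 (0.0725) or db/m vehicle 3 (0.0723). Lists without a call (camera adjusted p) were actin and adhesion (0.464), apoptosis and p53 (0.393), autophagy (0.667), cell cycle (0.974), complement (0.362), extracellular matrix (0.483), endoplasmic reticulum stress (0.529), immediate early and stress (0.12), inflammation (0.054), interferon (0.682), lipid synthesis and uptake (0.483) and lymphocyte (0.592).

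At an unadjusted p under 0.05, edgeR found 578 genes, 277 higher and 301 lower with puerarin. DESeq2 called 15 genes (12 higher and 3 lower), limma 0, and limma with library weights 1. Groups were separated for 443 genes, 3.23% against 5.71% by chance. Without db/db puerarin S144, edgeR called 5 genes, which were Xist (higher) and the Y-linked Kdm5d, Uty, Eif2s3y and Ddx3y (lower). These 5 were named after their values were seen.

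Puerarin-treated db/db mice were also set against db/m mice on vehicle, where genotype and drug differ together and the libraries with high Xist lie on the puerarin side. Expression of 20 genes rose and 5 fell. Adm, which encodes the vasodilator peptide adrenomedullin, was at 94.9 ± 1.57 CPM (SD, n = 3) against 26.7 ± 2.59 CPM (SD, n = 4). The genes that rose included Gpihbp1 (120 ± 32.4 against 49.2 ± 9.45 CPM) and the fatty acid binding protein gene Fabp4 (105 ± 23.3 against 43.7 ± 8.43 CPM). Sele, the endothelial adhesion molecule E-selectin, was at 12.3 ± 3.63 against 4.76 ± 1.32 CPM, and Foxc2 fell to 101 ± 12.3 from 160 ± 25.4 CPM.

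Adm had a log2 fold change of 1.85 (SE 0.22, edgeR adjusted p = 0.042), with 1.88 within the S-number and 1.78 within the group-tag libraries. Gpihbp1 was at 1.35 (SE 0.2, edgeR adjusted p = 0.0451), Fabp4 at 1.26 and Sele at 1.51 (SE 0.2 and 0.24, edgeR adjusted p = 0.0455 for both). Hdc, which makes histamine, rose by 1.56 (edgeR adjusted p = 0.0451), and the calcium-binding protein genes S100a4 and S100a6 rose by 1.19 and 0.84 (edgeR adjusted p = 0.0451 for both). Lgals1 rose by 1.19, the ribonuclease gene Rnase4 by 1.09 and the ubiquitin ligase gene Neurl1b by 0.75 (edgeR adjusted p = 0.0451 for each). Ctla2a, a cathepsin inhibitor, rose by 0.97 (edgeR adjusted p = 0.042), the ceramidase gene Acer2 by 0.90 (edgeR adjusted p = 0.0454) and the taurine transporter gene Slc6a6 by 0.72 (edgeR adjusted p = 0.0455). Foxc2 fell by 0.61 (SE 0.09, edgeR adjusted p = 0.0454). The other 4 lower genes were Dkk3 (-1.20) and Slc22a7 (-3.19), each with an edgeR adjusted p of 0.042, and the receptor genes Adra2c (-1.14) and Mc4r (-2.08), each with 0.0451. These 4 lie in the lowest 25% of genes by expression, outside the rule for named genes, and were chosen after their values were seen. Over the other settings Slc22a7 ranged from -3.47 to -0.93 and Mc4r from -2.22 to -0.91. Of 33 such settings, the call was kept in 19 for Adm, 15 for Foxc2, 14 for Gpihbp1, 13 for Sele and 9 for Fabp4. Kcnj12 and Aebp1 had log2 fold changes of -0.65 and -0.59 (edgeR adjusted p = 0.0551 and 0.0595). The dipeptidase gene Cndp2 was at -1.63 (edgeR adjusted p = 0.0551) and the calcium channel subunit gene Cacna2d2 at -1.20 (edgeR adjusted p = 0.0608).

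Cell cycle genes rose as a list (median 0.32, 19 of 22 higher, camera adjusted p = 3.54e-06; adjusted p = 0.647 with an estimated correlation), with 4 past the test when adjusted over the list alone. Cdk1 was at 2.13 (edgeR adjusted p = 0.13). Inflammation genes rose as a list (median 0.11, camera adjusted p = 0.000393; adjusted p = 0.671 with an estimated correlation). Sele passed over all genes and 5 members passed when adjusted over the list alone, with Tlr4, a receptor for bacterial lipopolysaccharide, at 0.86 and Icam1 at 0.73 (edgeR adjusted p = 0.126 and 0.18). Angiogenic genes rose as a list (median 0.1, camera adjusted p = 0.000398; adjusted p = 0.36 with an estimated correlation). Adm passed over all genes, and 6 members were higher and 1 lower when adjusted over the list alone. Ednrb was at 1.09 and Edn1 at 0.70 (edgeR adjusted p = 0.0678 and 0.121). These 3 calls held without each of the 11 libraries. Podocyte genes were not called (22 of 34 lower, camera adjusted p = 0.0618), nor were myeloid genes (camera adjusted p = 0.15).

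The other 8 calls were each lost without at least 1 library. Apoptosis and p53 genes were higher (median 0.1, camera adjusted p = 0.0326; adjusted p = 0.36 with an estimated correlation), with Cdkn1a, a cell cycle inhibitor, at 0.72 (edgeR adjusted p = 0.0608). That call was lost without db/db puerarin S144 (camera adjusted p = 0.108) or db/m vehicle S184 (0.0809). Ribosomal protein genes were higher (median 0.12, camera adjusted p = 9.32e-05; adjusted p = 0.826 with an estimated correlation) and were lost without db/db puerarin 2 (0.158). CREB targets were higher (median 0.24, camera adjusted p = 0.0216; adjusted p = 0.671 with an estimated correlation), with Crem at 0.54 (edgeR adjusted p = 0.136). They were lost without db/db puerarin 2 (camera adjusted p = 0.192) or db/m vehicle 3 (0.0864). Glomerular endothelial genes were higher (median 0.05, camera adjusted p = 0.0216; adjusted p = 0.826 with an estimated correlation) and were lost without db/db puerarin S144 (0.703), db/m vehicle S184 (0.412) or db/m vehicle 2 (0.138). They were lost with no name form term too (camera adjusted p = 0.146). Interferon genes were lower (median -0.18, camera adjusted p = 0.0216; adjusted p = 0.826 with an estimated correlation) and were lost without db/m vehicle S185 (0.0684), db/db puerarin 2 (0.672) or db/m vehicle 3 (0.0864). Fatty acid oxidation was called higher with 18 of 32 members higher (median 0.03, mean 0.3, camera adjusted p = 0.0326; adjusted p = 0.826 with an estimated correlation), and the uncertain Cyp4a14 was at 3.69 (edgeR adjusted p = 0.0608). It was lost without db/m vehicle S185 (camera adjusted p = 0.499), db/db puerarin 2 (0.476) or db/m vehicle 2 (0.212). It turned downward without puerarin 2 and 3, a setting that leaves S144 alone and was also chosen after seeing the data. Lymphocyte genes were lower (median -0.34, camera adjusted p = 0.0326; adjusted p = 0.826 with an estimated correlation) and were lost without db/db puerarin S144 (0.397), db/m vehicle S185 (0.0857), db/db puerarin 2 (0.0629) or db/m vehicle 3 (0.0864). Proximal tubule genes were lower (median -0.11, camera adjusted p = 0.0495; adjusted p = 0.826 with an estimated correlation), with Slc7a13 at -2.99 (edgeR adjusted p = 0.076). The Slc7a13 value was not separated from a sex difference between the groups. The proximal tubule list turned upward without db/db puerarin S144 (camera adjusted p = 0.894) or db/m vehicle S184 (0.963). The tubule level was -1.31 in db/db puerarin S144 and -0.89 in db/m vehicle S185. With the tubule level as a covariate the glomerular endothelial call (camera adjusted p = 0.419) was lost. So were the apoptosis and p53 and lymphocyte calls (0.0818 for both). Lists without a call (camera adjusted p) were actin and adhesion (0.264), antioxidant (0.0539), autophagy (0.718), collecting duct (0.718), complement (0.718), extracellular matrix (0.124), endoplasmic reticulum stress (0.238), erythroid (0.373), glycolysis (0.647), immediate early and stress (0.124), lipid synthesis and uptake (0.134), loop and distal (0.373), mesangial (0.261), NADPH oxidase (0.854) and oxidative phosphorylation (0.62).

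At an unadjusted p under 0.05, edgeR found 1410 genes (738 higher and 672 lower), and DESeq2 called 297. Groups were separated for 1050 genes, 7.65% against 5.71% by chance. Without db/db puerarin S144, 6 genes passed, and 0 of them were among the 25. There were 74 without db/db vehicle 1 (25 shared), 40 without db/db vehicle 3 (24 shared), 2 without db/db puerarin 3 (both shared) and 1 without db/m vehicle 2 (shared). It was 0 in edgeR without db/db vehicle S152, db/db vehicle S153, db/m vehicle S184, db/m vehicle S185, db/db puerarin 2 or db/m vehicle 3. In an alternative chosen after seeing the data, edgeR called 0 genes without db/m vehicle S184 and S185 (1073 at an unadjusted p under 0.05). Another left out the Xist-high libraries db/db puerarin 2 and 3. It kept only S144 in the puerarin group, so its count decides nothing about the 25 genes. DESeq2 was run on all libraries only.

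The series title names Gnai1, which encodes an inhibitory G-protein alpha subunit that lowers cAMP, and the cAMP and protein kinase A pathway. Gnai1 was at 52.3 ± 3.86 CPM in db/m (SD, n = 4), 70.2 ± 10.5 in db/db on vehicle (SD, n = 4) and 71.8 ± 17.4 in db/db on puerarin (SD, n = 3). All db/db libraries of both arms, from 58.2 to 91.4 CPM, lay above the 4 db/m libraries, from 48.1 to 57.3 CPM. The log2 fold change was 0.41 for db/db against db/m on vehicle (SE 0.1, edgeR adjusted p = 0.182), with 0.54 within the S-number and 0.29 within the group-tag libraries. It was 0.49 for puerarin-treated db/db against db/m (SE 0.11, edgeR adjusted p = 0.126), and 0.08 for puerarin against vehicle in db/db (SE 0.11, edgeR adjusted p = 0.973). Without db/db puerarin S144 the last value was -0.05. Exact two-sided permutation tests of Gnai1 gave p = 0.0286 for db/db against db/m over 70 assignments and p = 0.0286 for puerarin-treated db/db against db/m over 35. Both are the smallest p that the exact test allows. The exact permutation p for puerarin against vehicle was 0.943. DESeq2 gave adjusted p = 0.0337 and 0.0118 for the 2 comparisons with db/m, and over all alternatives the adjusted p ranged from 0.0253 to 0.998 and from 0.0118 to 0.803. Gnai1 lies on chromosome 5 (18265134 to 18360413, minus strand, mm10).

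**Figure D4:**
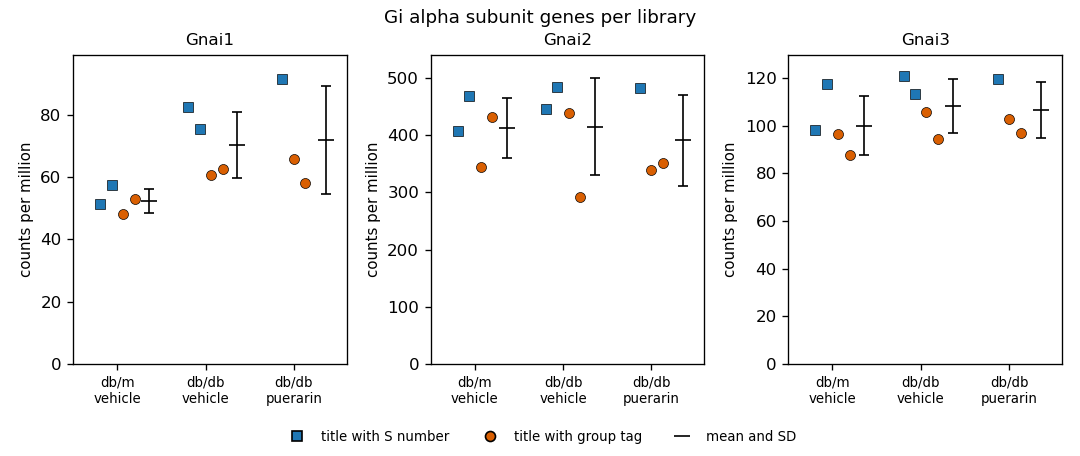
CPM of Gnai1, Gnai2 and Gnai3 in each library of the 3 groups, with group means and SD; squares mark S-number titles and circles group-tag titles. Gnai1 ranged from 48.1 to 57.3 CPM in db/m and from 58.2 to 91.4 CPM in the db/db libraries.

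The other inhibitory subunit genes did not pass in any comparison. Gnai2 was at 0.00, -0.04 and -0.04 and Gnai3 at 0.12, 0.01 and 0.13 for db/db against db/m, puerarin against vehicle, and puerarin-treated db/db against db/m (smallest edgeR adjusted p = 0.669). The catalytic subunit genes of protein kinase A, Prkaca and Prkacb, were at 0.02 and 0.01 for db/db against db/m (edgeR adjusted p = 0.954 and 0.981) and at -0.01 and -0.06 for puerarin against vehicle (edgeR adjusted p = 0.999 and 0.971). The regulatory subunit gene Prkar1b was at 0.74 and the coactivator gene Crebbp at -0.43 in db/db against db/m (edgeR adjusted p = 0.138 and 0.199). With puerarin, Crebbp was at 0.41 and the adenylate cyclase gene Adcy3 at -0.23 (edgeR adjusted p = 0.967 for both). The list of inhibitory G-protein and cAMP pathway genes (39 measured) was not called in camera (adjusted p = 0.591, 0.106 and 0.537). When adjusted over the list alone, 2 members were higher and 2 lower in db/db against db/m. Lepr, the gene of the db allele, was at 8.69 ± 2.41 CPM in db/db and 9.62 ± 1.24 CPM in db/m on vehicle (log2 fold change -0.18, edgeR adjusted p = 0.751; exact permutation p = 0.514). The db allele alters Lepr splicing, so a value over the gene does not check the labels.

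Whether puerarin moved genes towards the db/m level was tested by setting both effects side by side. Since puerarin against vehicle had 0 genes past the edgeR test, the number past both tests had to be 0 and says nothing about reversal. At an unadjusted p under 0.05 in both, 140 genes had opposite signs, and 1 gene passed both tests in DESeq2 and in limma with library weights. Among the genes that fell in db/db, the puerarin effect was 0.09 for Foxc2, 0.09 for Aebp1, 0.13 for Kcnj12, 0.08 for Dkk3, 0.39 for C130021I20Rik and -0.66 for Slc22a7 (edgeR adjusted p = 0.967 for each except Dkk3, 0.976). Both effects use the same db/db vehicle libraries, which gives a negative correlation with no effect at all. Across 13734 genes, which are not independent replicates, Pearson's r was -0.42 and Spearman's rho -0.38. In 100 simulations of unchanged groups sharing those libraries, r averaged -0.46, from -0.49 to -0.42. The covariance was -0.0362, outside the simulated range of -0.0271 to -0.0219 (mean -0.0242, a difference of -0.012). The 140 genes compare with 134 in the simulations (110 to 169) and 29.9 for independent lists, and 29 genes of the same sign with 2.26 (0 to 8). Each gene was simulated independently, so the simulated ranges leave out the spread of genes that move together. A value outside them, as for the covariance, therefore decides nothing. With the db/db vehicle libraries split so that each effect used its own, r was 0.09, 0.08, -0.02, -0.03, 0.11 and 0.09 in the 6 splits, and the covariance 0.0101, 0.00862, -0.0024, -0.00318, 0.0138 and 0.0102.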

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

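The check of Xist was chosen only after its values were seen. In the groups of 4, the highest or lowest library of each of 101 genes chosen for the text was set against the other 3 by Dixon's test, and 11 of 202 checks stood out. Chance flags about 1 in 20, which would be 10.1 here, so the number as a whole is near what chance gives.

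In db/db mice on vehicle, library 1 stood apart with Cacna2d2 at 25.5 CPM, where the other 3 had 14.7 to 16.4. Nox4 was at 31 CPM in the same library, where the others had 198 to 211. Library S153 had Lgals1 at 64.3 CPM against 39.9 to 43.2. Library 3 had Mt2 at 75.3 CPM against 41.6 to 45.7, and Xist at 6.47 CPM against 0.726 to 1.43.

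In db/m mice, library S184 had Nox4 at 249 CPM, where the others had 48.3 to 76.9, and Adm at 22.8 CPM against 27.9 to 28. Library S185 had Fam214a at 31.6 CPM against 47.6 to 48.9, Mc4r at 11 CPM against 5.28 to 5.63, and Pde4d at 19.2 CPM against 16.7 to 16.9. Library 2 had Nphs1 at 1500 CPM against 1210 to 1250. Nox4 is made by proximal tubule cells among others, and the proximal tubule level was lowest in db/db vehicle 1 (-1.16) and highest in db/m vehicle S184 (1.36).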

How the results depend on the processing

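The alternatives chosen only after the result was seen were robust edgeR, relative log expression factors, limma on the authors' log2 values, the tubule covariate, lists in the group-tag libraries alone, and the fits without puerarin 2 and 3 or without db/m S184 and S185. Counts of genes are given below for db/db against db/m (6 in the main test), puerarin against vehicle (0) and puerarin-treated db/db against db/m (25), in that order. The cause was not tested, except where fewer samples enter a fit.

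The gene counts were 1 and 5 in the first and last comparison with no name form term, 2 and 5 with only the 2 groups compared, and 0, 1 and 1 in the group-tag libraries alone, with 0 shared with the main test. In the S-number libraries alone 7, 0 and 2 genes passed, all higher in db/db and 0 of them among those of the main test, whose 6 were all lower. There the lone puerarin library is assumed to vary like the others. DESeq2 gave 290, 15 and 297, and limma with library weights 909, 1 and 115; each gave 1 gene in the reversal. The last count was 2 with limma at a pseudocount of 4 and 3 with quantile normalization. The counts were 13 and 1 in limma without trend, and the first was 13 on the authors' log2 values. The first and last counts were 0 and 0 without db/m S184 and S185, and 91 and 337 with the tubule covariate. Without puerarin 2 and 3 only S144 is left in the puerarin group, so the last count decides nothing and is not given. Gnai1 passed in DESeq2 (0.4 and 0.49 on the log2 scale), with library weights (0.43, db/db against db/m) and with the tubule covariate (0.46, puerarin-treated db/db against db/m). Leaving out 1 library at a time, the counts ranged from 0 to 82, 0 to 5 and 0 to 74, and Gnai1 from 0.34 to 0.48, -0.05 to 0.17 and 0.36 to 0.58.

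Whether the replicate numbers pair the samples was not settled. Deviations from the fit of group and name form correlated at 0.26 (db/db vehicle 3 with puerarin 3) and -0.23 (db/db vehicle 3 with db/m 3). They correlated at -0.18 (puerarin 2 with db/m 2) and -0.16 (puerarin 3 with db/m 3). Such deviations are constrained within small groups, so these values do not decide it. With the replicate block, in which number 1 held only db/db vehicle 1, 56, 0 and 49 genes passed.

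Of 29 lists, 13, 16 and 11 were called. With an estimated correlation 0, 0 and 0 were, and with fry 1, 0 and 1, the apoptosis and p53 list both times (adjusted p = 0.0133 and 0.00577). Puerarin against vehicle had 8 with no name form term, 8 with the tubule covariate and 7 in the group-tag libraries; the last comparison had 17 without puerarin 2 and 3. Leaving out 1 library gave 7 to 15, 6 to 16 and 10 to 14 lists.

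No gene changed direction with a call in either fit, and 41 list results did, all by camera adjusted p. List fits with libraries left out or with the covariate used the preset correlation of 0.01 only. For puerarin against vehicle, leaving out 1 library turned antioxidant (range 0.000486 to 0.907), collecting duct (1.34e-09 to 0.748), fatty acid oxidation (2.69e-07 to 0.977) and oxidative phosphorylation (2.42e-10 to 0.465) up without S144. It turned fatty acid oxidation and proximal tubule (5.51e-09 to 0.894) up and mesangial (2.69e-07 to 0.977) down without db/db vehicle 3, and interferon (0.0165 to 0.945) up and ribosomal protein (5.66e-06 to 0.616) down without puerarin 2. Without puerarin 2 and 3, erythroid (0.728) and interferon (0.00766) turned up and ribosomal protein down (0.196). With the tubule covariate, antioxidant (0.0202), fatty acid oxidation (0.00821), oxidative phosphorylation (1.59e-08) and proximal tubule (1e-07) turned up, and glomerular endothelial and podocyte (0.944 for both) down. The covariate is the mean of the tubule lists, whose effects then nearly cancel. Turns of the proximal tubule list with it, here and below, therefore decide nothing. In the group-tag libraries, antioxidant (0.807), collecting duct (0.433), fatty acid oxidation (0.336), loop and distal (0.705) and oxidative phosphorylation (0.0037) turned up.

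For puerarin-treated db/db against db/m, leaving out 1 library turned proximal tubule (range 0.000219 to 0.963) up without S144 or db/m S184, collecting duct (0.000303 to 0.718) and loop and distal (0.00251 to 0.725) up without S144, and oxidative phosphorylation (4.72e-06 to 0.938) down without puerarin 2. Proximal tubule also turned up without db/m S184 and S185 (0.579), with the tubule covariate (0.516) and in the group-tag libraries (0.208), where collecting duct (1.89e-06) and loop and distal (0.0103) turned up and glomerular endothelial down (0.958). Without puerarin 2 and 3, oxidative phosphorylation (1.02e-08) and fatty acid oxidation (0.4) turned down and interferon up (0.395). For db/db against db/m, proximal tubule turned down without db/db vehicle 3 (range 0.000151 to 0.988) and with the tubule covariate (9.79e-05), where oxidative phosphorylation turned down too (0.722), and endoplasmic reticulum stress turned down without db/m S184 and S185 (0.0444).

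Of the single gene values outside the leave-one-out fits, 2912 kept direction and side of the threshold, 169 gained a call, 203 lost it and 60 moved. For lists these were 371, 37, 124 and 51, with 26 turned. The correlation of the effects was -0.56 to -0.25 in the other fits, in all of which shared libraries alone give a negative value. That value was simulated for the main fit only. With separate vehicle libraries it was -0.03 to 0.11. In the simulations only 14% to 32% of genes changed 1.5-fold were found, so smaller changes were mostly below detection.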

Other observations

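Tests chosen only after the result was seen were those for mixed RNA, for more tubule of every segment, for genetic background and for glucocorticoid exposure, and the splits that keep the make-up by title form or group; the others, including the splits of all samples, were set before. Libraries with a group tag in the title differed from those with an S number in 957 genes by edgeR, 776 higher and 181 lower. The contractile genes Acta2, Myh11 and Cnn1 were higher with a group tag by 1.74, 2.32 and 3.29 on the log2 scale, and the immediate early genes Fos and Egr1 were at -1.57 and -1.5. These 5 were named after their values were seen. Of 24 immediate early and stress genes, 23 were lower, 12 past the test over all genes and 20 when adjusted over the list alone (camera adjusted p = 1.56e-12; adjusted p = 0.358 with an estimated correlation). The form was a term in every main fit.

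Only 1 of 40 splits of the libraries reached 957 genes, the real split by title form, and the highest other had 225. Among 40 of the 108 splits that kept the groups as balanced as the real one, the highest other had 0. The real split was 2.5% of those run, so chance is unlikely but not excluded. More tubule of every segment is not excluded. Proximal tubule genes had a median of -0.43, and loop and distal and collecting duct genes 1.28 and 1.29. Both lay 1.72 above it (95% bootstrap interval 1.55 to 1.92 for loop and distal). That interval resampled genes, which move together, and not libraries. The proximal tubule list had a fry adjusted p of 0.453. Its levels overlapped, at -0.47 to 1.36 with an S number and -1.16 to 0.98 with a group tag. Library size is excluded, with 939 genes after thinning to the smallest total, and so are trends with transcript length and GC content, with 964 genes after their removal against 930 before. Which sequencing site, day or dissection the forms stand for remains open and may account for it. No biological explanation was tested.

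Libraries db/db puerarin 2 and 3 carry Xist and lack Y-linked signal although the mice are labelled male. A mixture of male and female RNA of 20% or more is excluded, since the median of the 4 Y-linked genes reached at most 10.3% of the other 9 libraries, and a smaller share stays open. The values argue against origin in db/m mice but do not exclude it. On 17 genes that separate db/db from db/m on vehicle, chosen without the puerarin libraries, they lay at 0.77 and 0.79. There db/m is 0 and db/db 1, and the db/db vehicle libraries lay at 0.95 to 1.07. The vehicle libraries that chose these genes all had low Xist, so the place of female db/m mice is not known. Female db/db mice, or libraries from outside the series, may be the source and were not told apart. A sex difference between groups is then an untested part of each puerarin comparison.

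Libraries db/m vehicle S184 and S185 stood apart from the other 9 in 7 genes, seen after their values: AA465934 (0.5 and 0.6 against 15.6 to 26.4 CPM), Wdfy1, Fndc5 and Zbtb16 lower, and Tlr12, Acsm3 and Ces1g higher. A different genetic background cannot be told apart from other causes. It was to set more genes apart (7) than any of the other 54 pairs, and db/db puerarin S144 with db/m vehicle S185 had 18, all lower. That pair holds the lowest tubule levels (-1.31 and -0.89), while 52 of the 54 other pairs had 0, so the bound does not decide. Lower glucocorticoid exposure, a candidate explanation since Zbtb16 is a responsive gene, cannot be told apart either. The mean of 12 other responsive genes was below the other 9 libraries (-0.18 to 0.45) in S185 (-0.41) and within them in S184 (-0.03), and 1 library does not exclude it.

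Regrouping the libraries of each comparison tested whether chance could give as large a result. For db/db against db/m, 2 of 35 splits gave at least the real 6 genes, so chance is not excluded. The other such split gave 2293 genes, which points to a structure of the samples: it set db/db vehicle S152, S153 and 3 with db/m S184 against db/db vehicle 1 with db/m S185, 2 and 3. The proximal tubule level, looked up afterwards, separated these sides, at 0.2 to 1.36 against -1.16 to -0.02. For puerarin against vehicle the real count was 0, so all 35 splits had to give as many (highest other 4) and the test decides nothing. For puerarin-treated db/db against db/m only the real split of 35 gave 25 genes (1 split, highest other 0). The title form is a term of the fit, and only 18 of the 35 splits keep its make-up, too few for a share under 0.05. Among these 18 the highest other was 0 for the 25 genes and also for the 6 genes of db/db against db/m. For lists, 20 of 35 splits gave at least 13 for db/db against db/m (highest other 20), 13 gave at least 16 for puerarin against vehicle (highest other 20), and 21 gave at least 11 for puerarin-treated db/db against db/m (highest other 16), so chance is not excluded.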
